A study of Mus musculus with 2 samples.

How the data were processed

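The series holds 2 single-cell RNA libraries from adult mouse submandibular glands, 1 per group, taken 7 days after retroductal transfer of GFP or rat Shh by adenovirus at 1e9 particles per gland. Per the labels' protocols, the libraries were made with the 10x Chromium 3' version 3 kit. The deposited files hold whole-number UMI counts per gene and barcode with no normalization, per the labels and the values themselves. The submitters' processing notes name Cell Ranger 2.0.2, Cell Ranger 3.1.0 and the genome build mm10, with no word on which version made which library. How barcodes were called as cells, whether several glands or animals were pooled, how the glands were dissociated and whether red cells were lysed are not given in the sources used here. Of 30909 features, 30766 (99.5%) matched a gene of the GENCODE vM21 annotation of mm10, from which gene positions were taken.

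Barcodes with at least 300 genes, at least 500 UMIs and at most 20% mitochondrial UMIs were kept, which left out 950 GFP barcodes and 4203 Shh barcodes. Doublets were called within each library with Scrublet in scanpy 1.11.5 and removed, 587 (5.55%) in GFP and 399 (2.82%) in Shh, against 8.46% and 11.3% at a rate of 0.8% per 1000 barcodes, so fewer were called than that rate gives, by more in the Shh library. The kept cells carried 49381031 UMIs in GFP and 82494455 in Shh. Over all deposited barcodes, the 10 genes with most UMIs took 12.2% of the UMIs in GFP and 31.6% in Shh. The barcode filter acts on libraries whose median depth was 4086 and 1739 UMIs, which bears on the share of every class with shallow cells.

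Both libraries were clustered together, without batch integration, on 2000 variable genes, 30 principal components and 20 neighbours, with Leiden clustering at resolution 1 in igraph 0.11.9 and seed 0, which gave 35 clusters. A cluster took a class name, written as X-like, from 25 marker lists fixed before the data were examined. The scoring rule was set after seeing the data. A marker counted where at least 10% of the cluster's cells carried it at 1.5-fold or more over the other clusters, and a name needed 3 such markers. Clusters 16 and 26 stayed unnamed because every marker of another class passed with a higher score, cluster 18 because markers of another class led its top 10 genes, cluster 14 because T cell markers spoke against its best name and cluster 12 because cell cycle genes led it. These 5 were compared by number where they held 100 cells of each library. A cluster held mostly by 1 library can reflect that library and not a cell type. Classes were compared where each library had at least 100 cells, which gave 5 classes and 3 clusters, of which 7 share no cells.

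UMIs were summed over the cells of a class in each library and set against the class total as CPM (counts relative to that total, on the usual CPM scale). Ratios are Shh over GFP, with an exact conditional binomial interval. Shares of cells have exact Clopper-Pearson intervals and single counts exact Poisson intervals, all at the 95% level. A count of 0 was given the limit of 3 counts. With 1 library per group no p-value was computed, since cells and genes are not replicates. In the text a fold is given as the larger over the smaller level, with its direction.

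The 25 gene lists were fixed before the data were examined. A list's value is the median log2 ratio, with a pseudocount of 1 CPM, over members with at least 10 UMIs in the class, for at least 3 members. Its interval is a binomial order-statistic interval over members, or their range with fewer than 6, and describes members, not animals. Its percentile was taken among 10000 random lists matched on expression in 20 bins, as a description of these libraries. To limit the effect of RNA free in the droplets, a member counted as at its own level where its CPM was at least 10% of that in the class with most of it, and a list was read only where at least 50% of its members were. That share was set after seeing the data, and lists below it are named as such where printed. The 10% limit does not remove all free RNA. The secretory gland gene Mucl1 passed it in the Shh library at 18.6% in T-like and 14.7% in NK-like cells.

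Genes named in the text follow a rule fixed beforehand. A gene needed at least 50 UMIs in the library with the higher CPM, in at least 5% of the class cells there, with at most 10% of them from 1 cell, and a CPM of at least 10% of that in the highest class. Mitochondrial, ribosomal and unnamed gene models were left out. Genes were ranked by the bound of the ratio's interval nearest to 1, which had to pass 1.5-fold, and the first 10 in each direction were named in macrophage-like and granular duct-like cells and the first 3 elsewhere. The rule gave endothelial-like and fibroblast-like cells 10 names too, but these held under 100 GFP cells. Members of the lists, Shh, Gli1, Ptch1 and Hhip could be named always. Some genes that these rules cover, among them a member of the Hedgehog sum fixed beforehand, are not reported here, and that sum is given over Gli1, Ptch1 and Hhip. Any other gene is said to have been chosen after its values were seen.

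The method was tested on simulated data, with 200 genes altered. The simulated class sums were Poisson counts around a profile shared by both libraries. They held no free RNA, no cluster mix and no variation between cells or libraries. The values below therefore check the handling of counting error only and do not give error rates for the real libraries. For the macrophage-like comparison (10361 genes), the ratio's interval held the true value for 95.5% of unaltered genes and 98.0% of altered ones. Intervals lay wholly beyond 1.5-fold for 2.99% of genes altered 1.5-fold, 80.6% of those altered 2-fold and 100.0% of those altered 4-fold, and for 0 unaltered genes. For the NK-like comparison (8460 genes) the same shares were 95.8% and 96.5%, then 1.49%, 77.6% and 100.0%, and 0 unaltered genes. Random unaltered lists fell outside the central 95% of percentiles in 6.50% and 5.00% of draws.

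Alternatives fixed beforehand were a strict filter (500 genes, 1000 UMIs, 10% mitochondrial), every barcode kept and classed by its 15 nearest cells, doublets kept, resolutions 0.5 and 2, each library clustered on its own, thinning to 1000 UMIs, a pseudocount of 10, list minimum 50 and named-gene minimum 20 UMIs, scaling by the median gene ratio or by totals without the 50 most abundant genes, the mean over cells per 10000 UMIs, and equal cluster weights. A share without B-like, plasma-like and T-like cells and cluster 18 was added after seeing the data. Near-identical copies were sought with BLAST 2.17.0 over the last 300 bases of each transcript, at 90% identity over 100 bases, against 20 matched genes per gene. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.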

Results

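Single cells were profiled from the submandibular glands of adult mice, salivary glands below the jaw, 7 days after adenoviral vectors had been instilled through the gland duct at 1e9 particles per gland. The vectors carried either GFP, a fluorescent marker protein, or the rat gene for Sonic hedgehog (Shh), a secreted signal received by Ptch1. Each group had 1 droplet library. The GFP library held 11528 barcodes and 55145902 UMIs (unique molecular identifiers, each standing for a captured RNA molecule), with medians of 4086 UMIs and 1335 genes per barcode. The Shh library held 18333 barcodes and 93628189 UMIs, with medians of 1739 UMIs and 654 genes. After filters and doublet removal, 9991 GFP cells and 13731 Shh cells remained, with medians of 1380 and 851 genes. When each cell was thinned to 1000 UMIs, the medians were 500 genes in 8408 GFP cells and 531 genes in 10541 Shh cells, with 1583 and 3190 cells too shallow to enter. With 1 library per group no test between groups was possible, and no difference given here has a replicate check. Every interval is at the 95% level and, except for gene list medians, covers counting error only.

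The mouse Shh gene (ENSMUSG00000002633, chromosome 5, 28456815 to 28467256 on the minus strand of mm10) had 0 UMIs in both libraries, which allows up to 0.0544 CPM (counts of a gene relative to all UMIs of the cells concerned, on the usual CPM scale) in the GFP library and 0.0320 CPM in the Shh library. The transferred insert was the rat gene, so a count of 0 at the mouse gene does not check the label of either library. Both libraries carried Y-linked transcripts, with 5531 and 4006 UMIs of Ddx3y in the GFP and Shh libraries, against 3 and 8 UMIs of Xist.

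The first comparison asked whether transcripts that respond to Hedgehog signalling differed between the libraries. Ptch1, the Shh receptor and itself a target of the pathway, had 361 UMIs in the GFP library and 541 in the Shh library (7.31 and 6.56 CPM of all kept cells), a ratio Shh over GFP of 0.897 (0.784 to 1.03). Gli1, the transcription factor most often used as a readout of the pathway, had 2 and 1 UMIs. Hhip, which binds Hedgehog ligands, had 3 and 2. Summed, the 3 genes gave 366 and 544 UMIs, or 7.41 and 6.59 CPM, a ratio of 0.890 (0.778 to 1.02), whose interval includes 1. This pooled ratio also follows the makeup of the libraries and cannot show whether a given class differed. The unnamed cluster 16 held 33.2% of the Shh UMIs and 0.304% of the GFP UMIs. Its sum stood at only 2.30 CPM in Shh, which lowers the pooled Shh value. Ptch1 lies on chromosome 13 (63508328 to 63573598), Gli1 on chromosome 10 (127329882 to 127341974) and Hhip on chromosome 8 (79965851 to 80058006).

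By class, Ptch1 was higher in the Shh library in NK-like cells, with 13 UMIs in GFP and 84 in Shh (4.34 and 11.6 CPM, ratio 2.67, 1.48 to 5.23). It was lower in cluster 12, a cluster of cycling cells, with 36 and 6 UMIs (ratio 0.239, 0.0822 to 0.572), but its mix of cells differed, with Igkc of B-lineage cells at 3.71% of its UMIs in GFP and 0.00406% in Shh. Endothelial-like cells had the highest Ptch1 levels among the classes drawn, 22.6 and 28.9 CPM, from 5 and 127 UMIs. In fibroblast-like cells, a usual target of Hedgehog ligands, the 3 genes summed to 3 and 16 UMIs, a ratio of 0.823 (0.236 to 4.41). The ratio of the sum was 0.838 in macrophage-like, 0.978 in T-like, 1.13 in duct-like and 1.10 in granular duct-like cells. The wider list of Hedgehog pathway components had medians of −0.12 (log2, Shh over GFP) in macrophage-like, −0.25 in NK-like, −0.40 in duct-like and −0.23 in granular duct-like cells. The medians of all genes, given below, were also negative in macrophage-like and both duct classes. The list stood at −0.46 (−1.21 to 0.89, the range of 4 members) in cluster 14 and −0.064 in cluster 20. It stood at 0.29 in T-like cells and 0.64 (−0.28 to 1.10, the range of 4 members) in cluster 12. With few GFP cells, it stood at 0.43 (−0.026 to 1.90) in endothelial-like and 0.94 (−1.43 to 1.53) in fibroblast-like cells. Proposed further targets of the pathway had a median of −0.32 (−0.88 to 3.82) in macrophage-like cells, a range set by Igf1 at the upper end and Snai1 at the lower.

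**Figure D1:**
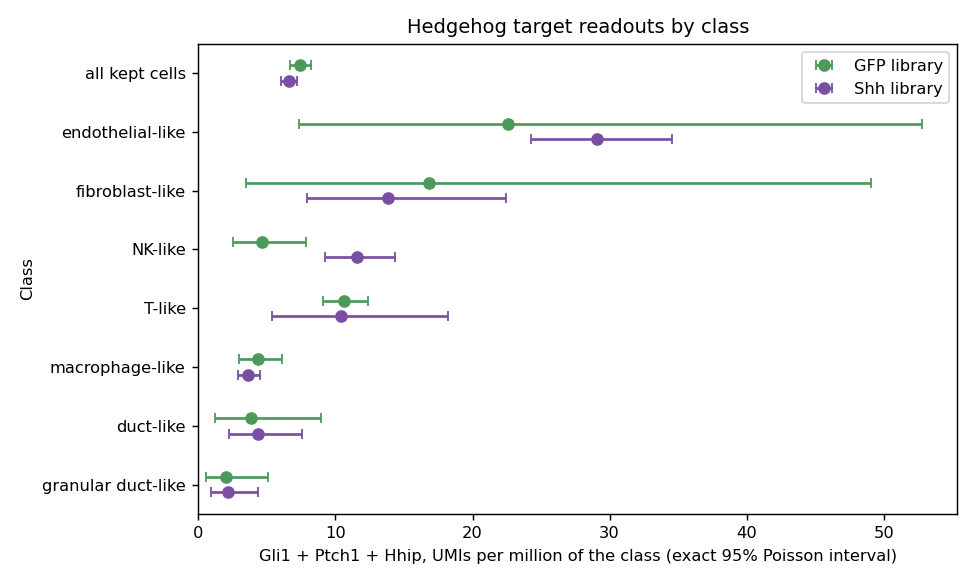
Summed UMIs of Gli1, Ptch1 and Hhip as CPM of the class (x axis) for 8 groups of cells (y axis), with green points for the GFP library, purple points for the Shh library and exact 95% Poisson intervals. Over all kept cells the points stand at 7.41 and 6.59 CPM, and the wide intervals of endothelial-like and fibroblast-like cells in GFP rest on 5 and 3 UMIs.

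The makeup of the recovered cells differed. Lymphoid cells made up 54.9% (53.9 to 55.9) of the GFP library and 12.8% (12.2 to 13.3) of the Shh library, 4.30-fold lower in Shh (4.07 to 4.54). Myeloid cells were higher in the Shh library, 15.2% against 35.9%, a ratio of 2.36 (2.23 to 2.51). Endothelial cells were also higher there, 0.791% (0.626 to 0.985) against 8.56% (8.09 to 9.04), a ratio of 10.8 (8.61 to 13.8), which was 17.1 under the strict filter and 16.6 with cells thinned to 1000 UMIs. Mesenchymal cells, all of them fibroblast-like, stood at 0.290% and 1.26%, a ratio of 4.34 (2.92 to 6.67). With each library clustered on its own, the mesenchymal ratio was 1.80 and the fibroblast-like ratio turned to 0.595, while thinning gave a mesenchymal ratio of 8.69. Epithelial cells stood at 25.0% and 37.6%, a ratio of 1.5 (1.43 to 1.58).

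Within the lymphoid cells, B-like cells numbered 2009 in the GFP library and 5 in the Shh library, 552-fold lower in Shh (236 to 1703). T-like cells stood at 24.2% and 1.73%, 14-fold lower (12.3 to 16.1). The B-like cells and the T-like clusters 9, 11, 21 and 22 held 4289 GFP cells (42.9%) and 17 Shh cells (0.124%), 347-fold lower (216 to 596). Among the leading genes were Lef1 in clusters 9, 11 and 22, and Ctla4 and Icos in cluster 21. NK-like cells were higher in the Shh library, 4.25% against 8.13%, a ratio of 1.91 (1.71 to 2.14). Plasma-like cells numbered 55 and 9. Macrophage-like cells made up 14.8% and 35.3% (ratio 2.38, 2.25 to 2.53) and conventional dendritic-like cells 0.330% and 0.532%.

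Of the epithelial cells, granular duct-like cells, which store kallikreins and growth factors, stood at 15.5% and 17.7% (ratio 1.14, 1.07 to 1.22). Duct-like cells stood at 8.97% and 13.7% (ratio 1.53, 1.41 to 1.65). Ionocyte-like cells numbered 41 and 143. Acinar-like cells numbered 0 and 64, where 0 of 9991 cells allows a share of up to 0.0300%, so the Shh share of 0.466% was at least 15.5-fold higher. That 0 depends on the naming rule, since every acinar-like marker passed in the unnamed cluster 16, with 10 GFP and 491 Shh cells. The acinar-like name itself is weak, since only 3 of its 7 markers passed. The listed acinar secretory products made up 2.03% of the Shh UMIs of these cells. That was below 4.36% in granular duct-like and 4.28% in duct-like cells, and 58.9% in cluster 16. Erythroid-like cells stood at 0.370% and 1.64%, a ratio of 4.42 (3.11 to 6.45). The 5 clusters left unnamed held 9.37% of the GFP cells and 9.78% of the Shh cells.

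Shares are parts of a whole, and the large lymphoid share of the GFP library lowers every other share in it. Without B-like, plasma-like and T-like cells and cluster 18, a choice made after the data were seen, the epithelial ratio turned to 0.783, the granular duct-like ratio to 0.595 and the duct-like ratio to 0.795, while the NK-like ratio was 0.996, the myeloid ratio 1.23 and the endothelial ratio 5.64. The duct-like ratio also turned to 0.804 under the strict filter, 0.722 with finer clusters, 0.653 with each library clustered on its own and 0.0817 with coarser clusters, where duct-like cells numbered 2413 in GFP and 271 in Shh. These settings cluster the cells anew, so cells can change class name. Under the strict filter duct-like GFP cells rose from 896 to 1052, while granular duct-like GFP cells fell from 1552 to 115. The granular duct-like ratio was 0.937 with thinned cells.

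**Figure D2:**
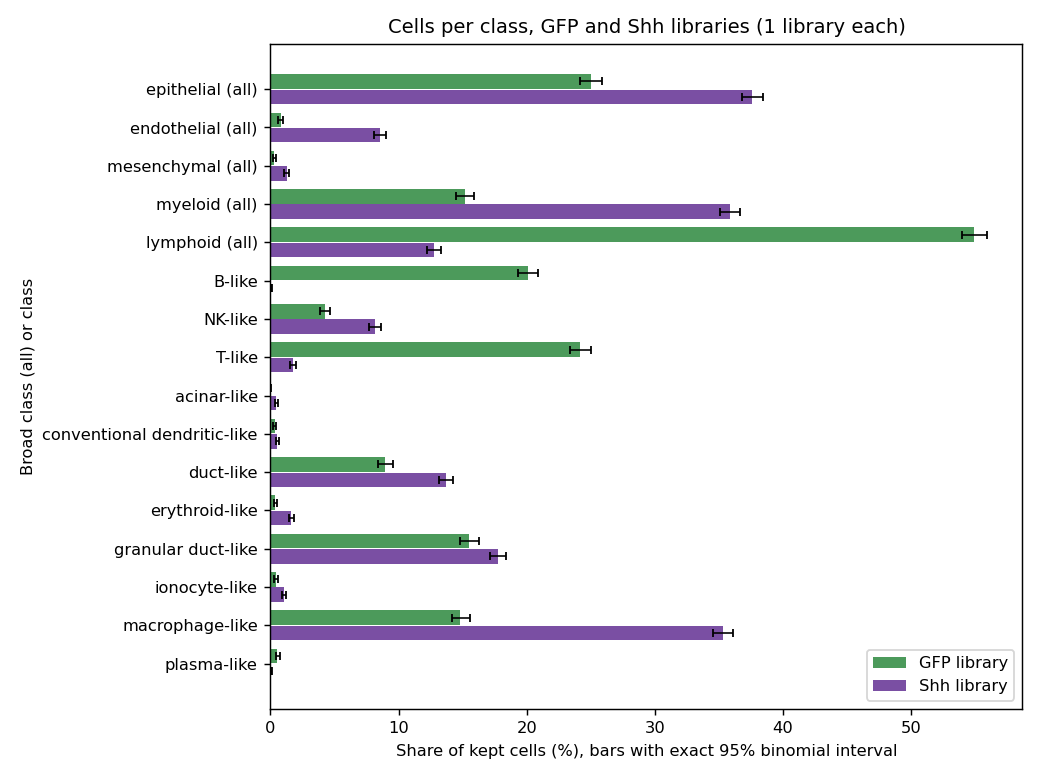
Share of kept cells in percent (x axis) for the broad classes, marked as all, and for the named classes (y axis), with green bars for the GFP library, purple bars for the Shh library and exact 95% binomial intervals. Lymphoid cells stand at 54.9% and 12.8%, and endothelial cells at 0.791% and 8.56%.

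Macrophage-like cells, the most numerous class of the Shh library (1482 GFP and 4851 Shh cells), differed most, by the fixed rule and leaving aside secretory gland genes, in Syngr1, Pmp22, Igf1, Fcrls and Ctsd on the higher side and in Dennd5b, H2-DMb2 and Dcstamp on the lower. Igf1, a growth factor, had 18 UMIs in GFP and 1097 in Shh and was 19.5-fold higher in Shh (12.3 to 33.0). Ctsd, a lysosomal protease, was 11.7-fold higher (11.1 to 12.4), from 1212 and 44591 UMIs. Fcrls, a receptor-like protein of tissue macrophages, was 16.2-fold higher (12.2 to 21.8), Pmp22 39.9-fold (18.2 to 109.0) and Syngr1 81.7-fold (27.9 to 397.2), the last from only 3 GFP UMIs. Dcstamp, which takes part in the fusion of macrophages, was 5.76-fold lower in Shh (5.35 to 6.21), and Dennd5b was 19.3-fold lower (13.3 to 28.7). H2-DMb2, a chaperone of antigen loading also made by B cells, was 6.29-fold lower (5.41 to 7.33).

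The same rule also named Map2 (3.80-fold lower) and Anxa6 (3.25-fold lower), and the class I genes H2-Q6 (3.18-fold lower) and H2-Q4 (2.78-fold lower), whose values are uncertain because members of that family share reads. It also named secretory genes of gland cells, Mucl1 (23.4-fold higher), Scgb2b26 (22.3-fold), Car6 (21.2-fold), Mucl2 (13.2-fold) and Prol1 (7.85-fold), which were higher in the Shh library in every class compared. Among genes chosen after their values were seen, Trem2, a lipid receptor, was 4.33-fold higher (4.04 to 4.64) and Mertk, a receptor for dying cells, 9.76-fold higher. Lyz2 was 3.30-fold and Apoe 2.07-fold higher, both also higher in every other class compared. Of the 7 classes and clusters that share no cells, Trem2 was higher beyond 1.5-fold in 5 and Ctsd in 4. Retnla had 7 and 1023 UMIs, of which 1005 of the Shh UMIs lay in cluster 17.

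On the reference, Igf1 lies on chromosome 10 (87858265 to 87937042), Ctsd on chromosome 7 (142375911 to 142388038), Fcrls on chromosome 3 (87250758 to 87263738), Pmp22 on chromosome 11 (63128982 to 63159547) and Syngr1 on chromosome 15 (80091334 to 80119501). Dcstamp lies on chromosome 15 (39745930 to 39760938), Dennd5b on chromosome 6 (148988071 to 149101680), Ifit3 on chromosome 19 (34583531 to 34588731) and Isg15 on chromosome 4 (156199424 to 156200818).

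Different clusters held most of this class in each library. In GFP these were clusters 8 (800 cells) and 15 (534), and in Shh clusters 1 (2228), 5 (1311) and 10 (785). Clusters 8 and 17 held over 100 cells of each library. Ctsd was 2.76-fold higher in Shh within cluster 8 and 11.4-fold within cluster 17, Igf1 8.09-fold and 31.8-fold, and Trem2 1.90-fold and 7.86-fold. Mertk stood at a fold of 1.03 (0.188 to 3.73) within cluster 8, from 13 and 3 UMIs, and Apoe was 1.17-fold higher there. Dcstamp was lower within both, 5.01-fold and 3.89-fold.

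**Figure D3:**
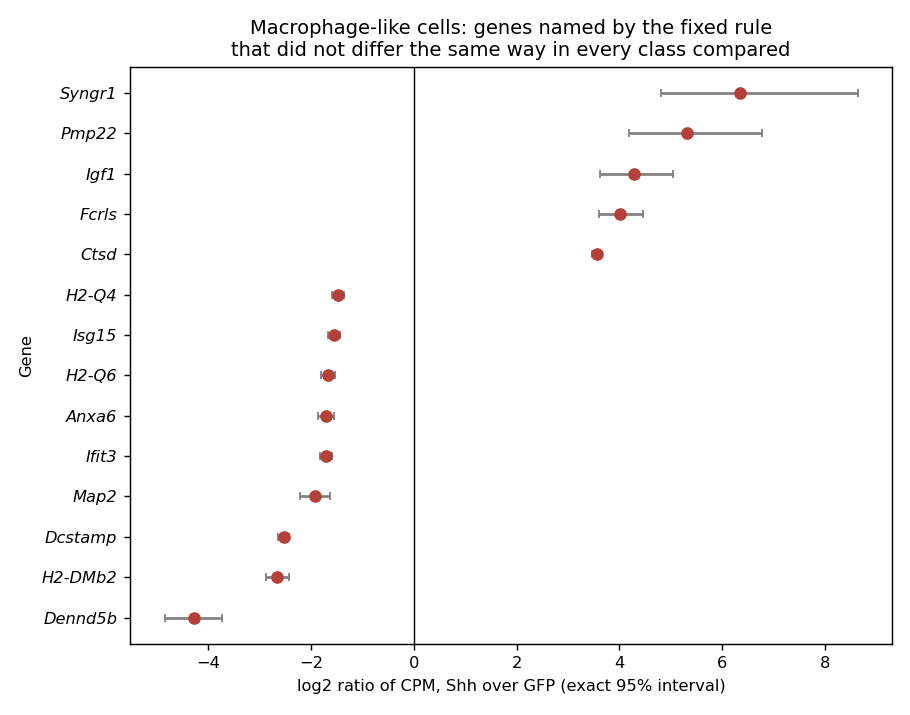
Log2 ratio of CPM, Shh over GFP (x axis, exact 95% interval), for 14 genes that the fixed rule named in macrophage-like cells (y axis), without those beyond 1.5-fold the same way in all 7 classes and clusters that share no cells. Syngr1 stands furthest to the right at 81.7-fold higher and Dennd5b furthest to the left at 19.3-fold lower.

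Gene lists fixed beforehand gave the following in macrophage-like cells, where the median of all genes was −0.10. All 20 interferon-stimulated genes measured were lower in the Shh library, with a median log2 ratio of −0.86 (−1.07 to −0.72, an interval over members of the list) that lay below every one of 10000 random lists matched on expression. Ifit3 was 3.26-fold lower (2.99 to 3.55) and Isg15 2.93-fold lower (2.72 to 3.16). All 9 genes of MHC class I presentation were lower, with a median of −0.52 (−0.72 to −0.29). All 7 of MHC class II presentation were lower too, with a median of −0.49 (−0.60 to −0.14). Inflammatory macrophage genes had 11 of 13 members lower (median −0.35, −0.69 to −0.027), with Cxcl10 2.19-fold and Il1b 1.91-fold lower. Chemokines had 15 of 18 lower (median −0.29, −0.78 to −0.035), while Ccl8 was higher, from 12 and 257 UMIs. Immediate early and dissociation stress genes had 17 of 18 lower (median −0.53, −0.71 to −0.38), with Fos 1.94-fold lower. The unfolded protein response had 15 of 15 lower (median −0.36).

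Resident macrophage genes had a median of 0.014 (−0.23 to 1.38), with Cx3cr1 at a fold of 1.01 and C1qa 1.14-fold lower against Mertk and Gas6 higher. The list of p53 and senescence genes stood at −0.16 and that of sex-linked genes at −0.15. The direction of several lists changed with the clusters used. Clusters 8 and 17 alone held at least 20 cells of each library, so clusters 1, 5, 10 and 15 were left out of the next values. Each got the same weight in both libraries, set by its cells over both. The interferon and class I medians then turned to 0.90 and 0.20, Ifit3 to a ratio of 2.36, Isg15 to 1.87 and the chemokine median to 0.38. Genes of the interferon list lead cluster 8 and help place cells in it, which limits these values. Within cluster 8, whose leading genes include Ifit3 and Cxcl10, Ifit3 was 2.64-fold higher in the 154 Shh cells, and within cluster 17 it was 2.48-fold lower. Inflammatory macrophage genes stood at 0.60 (−0.46 to 2.13) within cluster 8, with 8 of 11 higher, Cxcl10 3.39-fold higher and Il1b 1.08-fold higher, and at −0.46 within cluster 17. Stress genes stood at −0.074 (−0.36 to 0.17) within cluster 8 and at −0.68 within cluster 17.

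**Figure D4:**
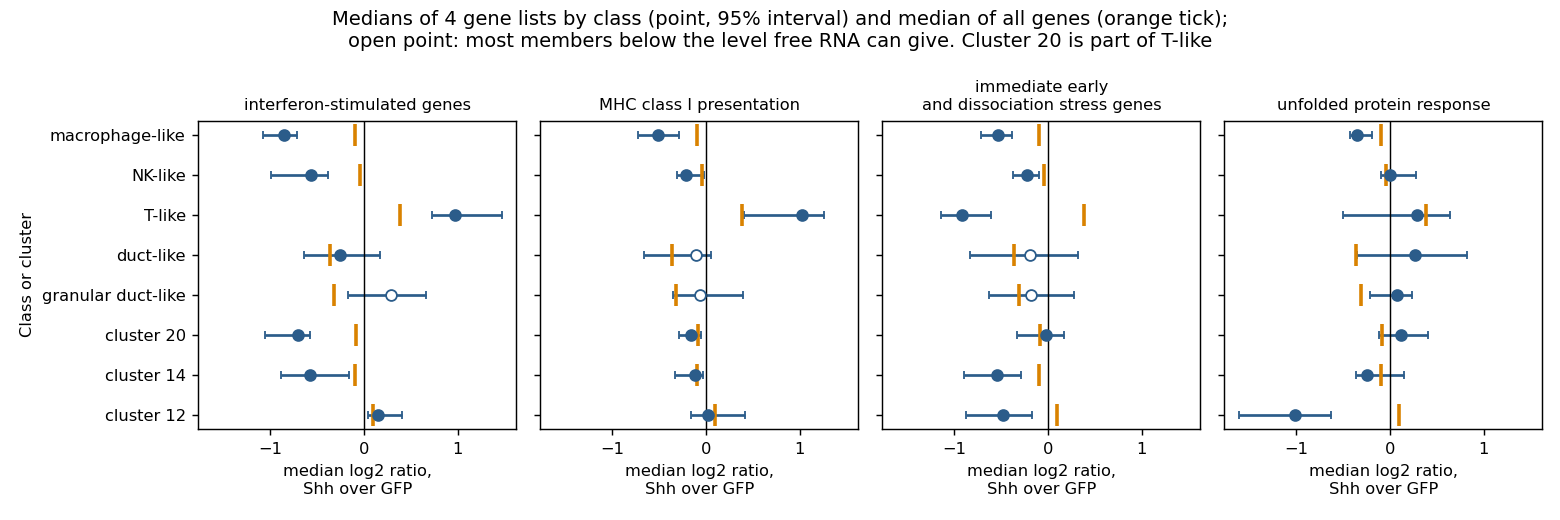
Median log2 ratio, Shh over GFP (x axis), of 4 gene lists in 5 classes and 3 clusters (y axis, where cluster 20 is part of the T-like class and clusters 12 and 14 are unnamed), with intervals over list members and an orange tick at the median of all genes; open points mark lists whose members mostly lay below the level that free RNA can give. Interferon-stimulated genes stand at −0.86 in macrophage-like, −0.57 in NK-like and 0.97 in T-like cells.

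In granular duct-like cells (1552 GFP and 2436 Shh cells) the main products were close to level between the libraries. The median of all genes was −0.32, and granular duct products had a median of −0.13 (−0.28 to 0.038), with 11 of 16 lower. Klk1, tissue kallikrein, was 1.70-fold higher in Shh (1.64 to 1.75), as it was by 1.57-fold to 5.60-fold in every class compared, and Egf stood at a fold of 1.00. Klk1b kallikreins are near-identical copies that share reads, so their single values are uncertain. This product list changed sign with the scaling, with a median of 0.19 when libraries were scaled by the median gene ratio. Under the strict barcode filter, with cells clustered anew, 115 GFP cells held this class name, while duct-like GFP cells rose from 896 to 1052. Cells thus changed class, and the Klk1 ratio, which turned to 0.564, compares a different set of cells there.

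Lower in the Shh library were Fdps, an enzyme of sterol synthesis (2.38-fold, 2.08 to 2.72), Gadd45a, a stress-induced gene (2.02-fold, 1.88 to 2.18), and Fbxw7, a ubiquitin ligase subunit (2.31-fold). So were Chd9 (3.24-fold), Grcc10 (2.81-fold), Nme2 (2.76-fold), Usp50 (2.75-fold), Gstp1 (2.53-fold) and Phb (2.24-fold). Several of these were not particular to this class. Of the 7 classes and clusters that share no cells, Gstp1 was lower beyond 1.5-fold in 6. Grcc10, Nme2 and Usp50 were each lower beyond 1.5-fold in 5. Under the strict filter, where GFP cells were removed or changed class, Gadd45a turned to a ratio of 1.24 and Fbxw7 to 1.64. Higher were the secretory genes Scgb2b26 (48.3-fold), Mucl1 (35.4-fold), Car6 (30.8-fold), Scgb1b27 (28.5-fold), Pip (25.7-fold), Scgb2b27 (21.2-fold), Prol1 (19.5-fold), Mucl2 (19.5-fold) and Mup5 (4 and 154 UMIs). The secretoglobin and Mucl genes belong to families of similar copies and are uncertain one by one. The unfolded protein response stood at 0.069, p53 and senescence genes at −0.32 (0.25 under the strict filter), neurotrophic factors and muscarinic receptors at −0.28 and sex-linked genes at −0.50. Most cells lay in cluster 4 in GFP (1462) and in cluster 0 in Shh (2429).

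Duct-like cells (896 GFP and 1880 Shh cells) had lower levels of Hmgcs1 and Fdps, both enzymes of sterol synthesis, in Shh. Hmgcs1 had 299 and 170 UMIs and was 3.73-fold lower (3.08 to 4.53), and Fdps had 579 and 378 and was 3.25-fold lower (2.85 to 3.71). Within cluster 7, which held both libraries, Hmgcs1 was 2.34-fold and Fdps 2.30-fold lower. The median of all genes was −0.36. Scgb2b26 (44.1-fold), Mucl1 (42.8-fold) and Scgb1b27 (29.4-fold) were higher. All 7 class II genes were higher in Shh, with a median of 0.69 (0.14 to 0.91), Cd74 by 1.66-fold, but the libraries were held by different clusters. Within cluster 7, where class II genes lay at levels that free RNA can give, 5 of 6 were lower (median −0.64, −0.96 to 0.29). Granular duct products stood at 0.25 (0.032 to 0.47), and turned to −1.45 under the strict filter and −0.76 with coarser clusters. Under those settings GFP cells changed class, and 1052 and 2413 of them were duct-like. The unfolded protein response stood at 0.26 (−0.35 to 0.82), and within cluster 7 at −0.33 (−0.55 to −0.17), interferon-stimulated genes at −0.25 (−0.64 to 0.17), p53 and senescence genes at −0.32 (0.033 under median gene ratio scaling), and macrophage trophic factors at −0.033. Cluster 7 held 855 of the GFP cells and cluster 3 held 1605 of the Shh cells.

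NK-like cells, whose clusters 6 and 23 held both libraries (425 GFP and 1117 Shh cells), had lower interferon-stimulated genes in Shh. Of the 20 genes, 18 were lower, with a median of −0.57 (−0.99 to −0.39), among them Isg15 2.48-fold and Irf7 2.01-fold. MHC class I presentation stood at −0.22 (−0.31 to −0.019) and stress genes at −0.22, with 15 of 18 lower. Effector genes of T and NK cells had a median of 0.064 (−0.16 to 0.58), with Gzmb 3.90-fold higher (3.65 to 4.17) and Gzma at a fold of 1.03. The rule named BC023719 (60 UMIs and 1 UMI, 145.0-fold lower, 25.1 to 5822) and Rasgrp2 (3.80-fold lower), with Mucl1 (48.9-fold), Car6 (42.7-fold) and Mucl2 (27.8-fold) higher. The unfolded protein response stood at 0.0023 and p53 and senescence genes at −0.012.

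In T-like cells (2417 GFP and 237 Shh cells) the fixed rule named 3 genes of resting T cells as lower in the Shh library. Igfbp4 was 21.9-fold lower in Shh (17.1 to 28.6), Ccr7, a lymph node homing receptor, 31.9-fold lower (16.8 to 69.9) and Lef1 16.6-fold lower (11.7 to 24.3). Naive and central memory genes had a median of −2.18 (−4.83 to −0.38) and effector genes 2.75 (1.21 to 3.25), where the median of all genes was 0.38. Scgb2b26 (70.2-fold), Mucl1 (59.3-fold) and Car6 (46.6-fold) were higher. Clusters 9, 11, 21 and 22 held most GFP cells and cluster 20 held 225 of the Shh cells, so these values compare different clusters.

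Within cluster 20, led by Cd8a and Ccl5 (137 GFP and 225 Shh cells), all 19 interferon-stimulated genes measured were lower in Shh, with a median of −0.71 (−1.06 to −0.57). Effector genes stood at −0.11, class I presentation at −0.16, naive genes at −0.60, cell cycle genes at −0.29 and the angiogenesis list at 0.14 (4 members). Gstp1 was 3.81-fold and Grcc10 2.59-fold lower, both also lower in most classes compared. Scgb2b26 (63.1-fold), Mucl1 (37.2-fold) and Car6 (33.4-fold) were higher.

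Clusters 12 and 14 were left unnamed and are compared by number. Cluster 14, led by Cd163l1, Tcrg-C1 and Il1rl1 (181 GFP and 382 Shh cells), had a median of all genes of −0.10, interferon-stimulated genes at −0.58 (−0.89 to −0.16) and stress genes at −0.55 (−0.90 to −0.29). Tcrg-C2 was 2.58-fold and Gstp1 2.75-fold lower, Gstp1 as in most classes compared. Car6 (79.6-fold), Mucl1 (50.9-fold) and Mucl2 (35.4-fold) were higher. Cluster 12, led by cell cycle genes such as Mki67 (342 GFP and 313 Shh cells), held cells of several kinds. Macrophage genes were higher there in Shh, Trem2 8.55-fold, Cd63 4.62-fold and Apoe 4.15-fold. Cd63 and Apoe were higher in every other class compared as well. Trem2 was higher beyond 1.5-fold in 5 of the 7 classes and clusters that share no cells. B cell genes were lower, Pou2af1 at least 71.7-fold (308 UMIs and 0), H2-DMb2 19.8-fold and Tnfrsf13c 12.7-fold. Cell cycle genes had a median of 0.043 (−0.20 to 0.36), alternatively activated macrophage genes 0.34, salivary progenitor genes −0.81 and the unfolded protein response −1.02. At a finer resolution the interferon list of this cluster turned from 0.14 to −0.91 the class II list from 0.40 to −0.34 and the chemokine list from 0.95 to −0.27, while the unfolded protein response stood at 0.0038.

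One set of genes differed the same way in all 7 classes and clusters that share no cells. In it, 23 genes were higher in Shh, mainly products of secretory gland cells such as Dcpp3 (median 92.3-fold), Bpifa2 (76.2-fold) and Car6 (42.7-fold), with hemoglobin genes such as Hba-a2 (8.35-fold), and Lyz2 (8.26-fold). The Dcpp genes are near-identical and uncertain one by one. The 12 acinar secretory products together made up 0.0936% of all kept UMIs in GFP and 20.8% in Shh. In macrophage-like cells they made up 0.0432% and 1.37%, and in NK-like cells, which do not make saliva proteins, 0.0213% and 1.05%. Cluster 16 (10 GFP and 491 Shh cells) held 33.2% of the Shh UMIs, and 58.9% of its UMIs there were these products. The acinar list had a median of 3.62 in macrophage-like and 4.44 in NK-like cells, the hemoglobin list 2.10 and 2.20 and the extracellular matrix list 1.05 and 1.39. Most members of each of these lists lay at levels that free RNA in the droplets can give.

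A smaller set of 10 genes was lower in the Shh library in all 7. Of these, 6 had their highest GFP level in B-like or plasma-like cells or in cluster 18, namely Cd79a (median 103.0-fold lower), Ebf1 (15.5-fold), Iglc1 (10.2-fold), Igkc (9.94-fold), Jchain (5.92-fold) and the gene model Gm10260 (419-fold). Gm10260 stood apart from the other 5, being 343-fold to 1597-fold lower over the 7. It had 11 near-identical copies, where the other 5 had none. Among the others were Gm8797 (4.15-fold), Gm10076 (2.07-fold) and Snrpg (1.77-fold).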

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

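The tests of blood, of depth and the barcode filter and of free RNA, and the split of the genes lower in every class into parts, were chosen after the results were seen. So was the use of equal cluster weights to judge the mix of clusters, although that weighting was among the alternatives fixed beforehand.

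Some gene lists went opposite ways in different classes of the same pair of libraries, and these differences were not tested, since each group has 1 library. Interferon-stimulated genes had a median log2 ratio (Shh over GFP) of 0.97 (0.72 to 1.47) in T-like cells, against −0.86 (−1.07 to −0.72) in macrophage-like and −0.57 (−0.99 to −0.39) in NK-like cells. MHC class I presentation stood at 1.02 (0.40 to 1.26) in T-like cells, against −0.52 (−0.72 to −0.29) in macrophage-like and −0.22 (−0.31 to −0.019) in NK-like cells. MHC class II presentation stood at 0.69 (0.14 to 0.91) in duct-like cells and at −0.49 (−0.60 to −0.14) in macrophage-like cells. In T-like cells the median of all genes was 0.38 and the libraries were held by different clusters, and within cluster 20 the interferon list stood at −0.71 and the class I list at −0.16. The duct-like libraries were also held by different clusters, and within cluster 7 the class II list stood at −0.64 (−0.96 to 0.29), with its members at levels that free RNA can give.

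The near absence of B-like cells and of 4 T-like clusters from the Shh library has several candidate explanations besides the transferred gene, whose effect cannot be separated from the single libraries. Blood left in the GFP gland would bring red cells, and the erythroid-like share was 4.42 times as high in Shh (3.11 to 6.45), which argues against it, although the neutrophil genes S100a8 and S100a9 stood at 422 CPM in GFP and 12 CPM in Shh and any red cell lysis is unknown. Depth or the barcode filter is argued against by the lymphoid ratio, which stayed between 0.205 and 0.262 under every alternative fixed beforehand. A piece of lymph node in the GFP sample remains open and had the values it needs. Genes of lymph node vessels and follicles summed to a ratio of 0.0460 (0.0388 to 0.0542), carried mainly by Glycam1 (1851 and 1 UMIs), with Madcam1 (44 and 1) and Cxcl13 (20 and 4) the same way and Fut7 (99 and 149) and Chst4 (2 and 0) not apart.

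The lower interferon-stimulated genes in macrophage-like and NK-like cells could come from the cells' state after Shh transfer or from technical sources. In NK-like cells the mix of clusters is argued against, since the median within cluster 6 was −0.60 (−0.86 to −0.39), and in macrophage-like cells it stays open. Cluster 17 gave −0.89 (−1.27 to −0.55), but the bound written beforehand left out cluster 8. That cluster held 54.0% of the GFP cells of the class, is led by list members and had a median of 1.31 (1.00 to 1.74). Both clusters, weighted alike in each library by their cells over both, gave 0.90. The value of cluster 8 cannot decide the question, since the genes compared also help place cells in it. Totals taken up by secretory RNA are argued against by a median of −0.76 (−0.98 to −0.62) in macrophage-like and −0.53 (−0.95 to −0.35) in NK-like cells under median gene ratio scaling. For free RNA, the intervals of the duct classes reached down to −0.64, short of the macrophage-like median of −0.86 but past the NK-like median of −0.57. This cannot decide the question, since within duct-like cluster 7, 12 of 16 list members measured lay at their own level. The duct libraries were also held by different clusters. Free RNA stays open in both classes.

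The set of 10 genes lower in Shh in every class could reflect how reads were assigned to near-identical copies, the more so as 2 Cell Ranger versions are named without their roles. Over the set, 40.0% (12.2 to 73.8) had such a copy against 14% of 200 matched genes, an interval that reaches below the matched share and leaves the set as a whole open. For the 60% with no such copy it is argued against, namely Snrpg and 5 of the 6 genes with their highest GFP level in B-lineage cells (all but Gm10260), for which free RNA of those cells is another candidate explanation that was not tested. Among the other 4 genes, Snrpg included, 75.0% (19.4 to 99.4) had a copy against 15%, an interval above the matched share. This cannot decide the question, since the split was made after the results were seen, holds 4 genes and was matched on expression alone. Exons shared with an overlapping gene were found for 10.0% (0.253 to 44.5) against 9.00%, so that explanation is argued against for the 90% without them and open for the rest.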

How the results depend on the processing

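The share without B-like, plasma-like and T-like cells and cluster 18 was the alternative, among these tests, chosen after the results were seen. No paired analysis was possible because each group had 1 library, and for the same reason no other splits of the samples could be made. All 27 Hedgehog readout values under the alternatives kept within the main interval. Of 754 list medians under alternatives, 692 kept within the main interval, 47 moved beyond it and 15, whose main interval lay off 0, changed sign. Of 634 values of named genes 453 kept within it, 176 moved and 5 reversed. Broad shares kept within it in 22 of 39 cases, moved in 16 and reversed in 1, and class shares in 52, 29 and 10 of 91. The rule could not be run for granular duct-like cells at resolution 0.5, which had under 100 GFP cells, nor for clusters 14 and 20 under the strict filter. Depth limits Gli1 and Hhip, at 3 UMIs or fewer in each library.

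Values that reversed and a selection of those that moved follow by setting, as share ratios, gene ratios or log2 list medians. The cause was not tested unless stated. With doublets kept, granular duct products in granular duct-like cells stood at 0.056. Equal cluster weights give a cluster the same weight in both libraries, by its cells over both. By construction they leave few clusters in each class. They gave ratios of 2.36 for Ifit3 and 1.87 for Isg15 and, in macrophage-like cells, 0.90 for interferon-stimulated genes, 0.20 for MHC class I and 0.38 for chemokines. In T-like cells they gave −0.70, −0.16 and, for effector genes, −0.11, and in granular duct-like cells −0.44 for granular duct products. With every barcode kept, the ratios were epithelial 1.42, lymphoid 0.205 and myeloid 2.53. Median gene ratio scaling put granular duct products in granular duct-like cells at 0.19 and p53 and senescence genes in duct-like cells at 0.033. With each library clustered on its own, ratios were duct-like 0.653, fibroblast-like 0.595, lymphoid 0.245 and mesenchymal 1.80.

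At resolution 0.5, the duct-like ratio was 0.0817, and duct-like medians were −0.76 for granular duct products and 0.059 for sex-linked genes. At resolution 2, cluster 12 had medians of −0.34 for MHC class II, −0.27 for chemokines, −0.91 for interferon-stimulated genes and 0.0038 for the unfolded protein response. There granular duct products stood at 0.36 in granular duct-like cells and the duct-like ratio at 0.722. Under the strict filter GFP cells were removed or changed class, with 115 granular duct-like and 1052 duct-like, against 1552 and 896 in the main setting. That filter gave granular duct-like ratios of 1.64 for Fbxw7, 1.24 for Gadd45a and 0.564 for Klk1. Medians were −0.39 for granular duct products and 0.25 for p53 and senescence genes, and −1.45 for granular duct products in duct-like cells. Share ratios under it were duct-like 0.804, endothelial 17.1, epithelial 1.94 and lymphoid 0.262. Thinning to 1000 UMIs turned the ratio of genes per cell from 0.617 to 1.06 and gave share ratios of endothelial 16.6, epithelial 2.01, granular duct-like 0.937, lymphoid 0.257 and mesenchymal 8.69. Without the B-like, plasma-like and T-like cells and cluster 18, ratios were NK-like 0.996, conventional dendritic-like 0.839, duct-like 0.795, endothelial 5.64, epithelial 0.783, granular duct-like 0.595, lymphoid 0.938, mesenchymal 2.26 and myeloid 1.23.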

Other observations

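The genes and gene groups of this part were chosen after their values were seen, and no tests of hypotheses were run on them. In the duct classes, most of 17 genes of cholesterol synthesis were lower in the Shh library. Their median log2 ratio was −1.02 (−1.37 to −0.58, over members) in duct-like cells, with 15 of 17 lower, and −0.56 (−0.96 to −0.33) in granular duct-like cells, with 16 lower, where the medians of all genes were −0.36 and −0.32. Idi1 was 3.14-fold (2.68 to 3.69), Acat2 3.23-fold and Fdft1 2.40-fold lower in duct-like cells, beside Hmgcs1 and Fdps. Within cluster 7, which held 855 GFP and 176 Shh cells, the folds were smaller, Idi1 1.92-fold, Acat2 2.02-fold and Fdft1 1.70-fold lower, and 13 of 14 genes were lower, with a median of −0.81 (−1.20 to −0.46). The same genes stood at −0.18 (−0.40 to −0.027) in macrophage-like and −0.14 (−0.23 to 0.13) in NK-like cells. In NK-like cells Gzmb, an effector protease, was 3.90-fold higher in Shh and Gzmc 2.39-fold, while Il7r was 2.61-fold lower. Gzmb was also higher within cluster 6, at 3.96-fold. Cluster 14 had higher Il1rl1, the receptor for IL-33, in Shh (58 and 500 UMIs, 4.70-fold, 3.57 to 6.28), with Il17rb 4.78-fold and Gata3 1.61-fold higher, while Il17a was 2.67-fold and Trdc 1.46-fold lower. That cluster passed both innate lymphoid and T cell markers, and a different mix of cells between the libraries was not tested.

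Classes with fewer than 100 GFP cells fell below the limit for comparing genes, so the values below rest on few cells. In endothelial-like cells (79 GFP and 1175 Shh cells), Aqp1, a water channel, was 6.48-fold higher in Shh (4.19 to 10.6), Slco2a1 8.18-fold and Plvap 1.71-fold. The mix of clusters differed, since cluster 28, led by Aqp1 and Slco2a1, held 4 GFP and 128 Shh cells, and cluster 19 held 55.7% of the GFP and 30.7% of the Shh cells. Aplnr had 2 and 739 UMIs, an 18.6-fold difference (5.12 to 153.6). Vcam1 was 4.87-fold (3.88 to 6.06), Cdkn1a 2.67-fold and H2-K1 1.56-fold lower. Of the angiogenesis and endothelial activation list, 13 of 16 members were higher (median 0.67, 0.22 to 3.16), while MHC class I presentation stood at −0.62 (−0.89 to −0.30) and p53 and senescence genes at −0.92 (−1.52 to −0.12). Stress genes were lower with them, 14 of 18 (median −0.63, −1.17 to −0.083), and inflammatory genes stood at −0.76 (−2.67 to 2.92). In fibroblast-like cells (29 and 173 cells) all 18 stress genes were lower in Shh (median −2.48, −2.91 to −2.08), interferon-stimulated genes stood at −1.66 and genes of extracellular matrix and fibrosis at 0.46 (0.033 to 1.26). Acinar secretory products made up 0.0196% of the UMIs of these cells in GFP and 11.9% in Shh, so RNA of gland cells weighs on these values. Conventional dendritic-like cells (33 and 73) had all 7 class II genes higher (median 0.86, 0.59 to 1.18), with Cst3 3.22-fold and Axl 8.35-fold higher. Resident macrophage genes stood at 2.30 (−1.16 to 3.08) there, with C1qa at 118 and 1007 CPM, so macrophage RNA was not excluded, and 16 of 18 stress genes were lower (median −1.07). Ionocyte-like cells (41 and 143) had class II genes at −2.39 (−3.34 to −1.70) and interferon-stimulated genes at −1.10, but cluster 34, with 0 GFP and 31 Shh cells, held 476424 of the 681163 Shh UMIs. Resident macrophage genes stood at −1.35 (−2.32 to 1.22) in this class and C1qa at 1427 and 523 CPM, so macrophage RNA in the few GFP cells was not excluded.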
